A study of Mus musculus with 9 samples.

How the data were processed

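The series holds 9 RNA-seq libraries of mouse peritoneal macrophages, 3 from each of 3 sorted populations, from mice carrying a tamoxifen-inducible Cre with EYFP under Cx3cr1 and a Cre-dependent tdTomato reporter. Per the labels, macrophages were sorted by flow cytometry, RNA was taken up with RNeasy Mini or Micro kits, the latter for small cell numbers, and libraries were made with the TotalScript low-input kit; the sort gates are not given in the sources used here. Per the labels' protocols, all mice were given complexes of 5 µg IL-4 with 25 µg anti-IL-4 antibody every other day from 4 days before harvest, which drives macrophages into alternative activation. The monocyte-derived group was harvested 4 days after 2 ml of thioglycollate, an irritant that draws blood monocytes into the peritoneal cavity. The converted group had received 2 ml of thioglycollate and a tamoxifen diet for 10 weeks before harvest. The labels give the resident group no further treatment. The titles number the libraries 1 to 3 in each group, and nothing in the labels says that libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical. The design text also names ATAC-seq, which was not analysed here.

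The deposited values are raw read counts per gene. Per the submitters' processing notes, the authors used TopHat2 2.1.0, HTSeq (no version given) and the genome build GRCm38; the annotation, the strand setting and the handling of reads with several alignments are not given in the sources used here. Reads of paralogs, overlapping genes and antisense partners can therefore not be told apart with certainty. Each file lists 47729 gene identifiers, of which 47224 were matched to GENCODE mouse release M21 (Ensembl 96, GRCm38) for symbols and coordinates. The other 505 held 0.064% to 0.108% of the reads of a library. The 5 summary lines per file that name no gene were left out of library sizes and tests. Reads in no gene made up 4.02% to 5.66%, ambiguous reads 4.47% to 4.68%, and the other 3 lines were 0 in every file.

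Counts were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): genes were kept with filterByExpr (minimum count 10, minimum total 15), scaled with TMM, and tested with the robust quasi-likelihood F-test in a single fit of all 9 libraries with 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 13223 genes tested, and a gene was called at an adjusted p under 0.05. Fold changes of genes with no read in a group are given as lower bounds against a floor of 3 reads over the group, and those with 1 to 3 reads as ratios with 95% counting intervals, which cover counting error only. Levels are reads scaled to library size (CPM) on TMM-scaled library sizes.

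Gene lists of macrophage programmes, technical signals and other cell types were written before the data were examined. The 26 lists with at least 4 tested members were tested with camera on log CPM (prior count 2, correlation preset to 0.01), adjusted over the lists of a comparison, and again with an estimated correlation. As an alternative they were tested with fry, which asks whether the members of a list move one way on balance and does not compare them with other genes. None of the lists passed with an estimated correlation in any of the 3 comparisons. Member counts are given over all genes and, where stated, adjusted over the list alone. Named genes followed a rule fixed at the same time. It takes the 6 largest changes in each direction per comparison among called protein-coding genes with non-overlapping libraries and at least 20 CPM in the higher group, leaving out predicted genes, RIKEN clones, olfactory genes and antigen receptor segments. It adds a set of key genes, up to 3 called members per macrophage list and direction (or the 2 highest expressed members where none was called), and the highest member of each list of other cell types. Xist, the further member of the B-cell list and the examples from the osteoclast list named in the closing part were chosen after their values were seen.

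The position of a library between both end states was its projection on the difference between monocyte-derived and resident libraries, with genes chosen on 2 libraries of each and the projected library held out. Comparisons that share the monocyte-derived libraries were set beside 20 simulations of unchanged groups. On simulated counts with changed genes, the converted versus resident test recovered 71% of 2-fold, 90.6% of 4-fold and 22.2% of 1.5-fold changes among 13078 genes tested, with 6 false calls. The 2-fold recovery was 79.6% for converted versus monocyte-derived and 67.6% for resident versus monocyte-derived. Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, protein-coding genes alone, the replicate number as a block, 2-group fits, and each library left out in turn. Chosen after seeing the data were the removal of genes on chromosomes X and Y, the split of the monocyte-derived libraries between both contrasts, positions without the lists of other cell types, and a B-cell index, the log2 summed CPM of the B-cell list, as a covariate in edgeR and camera; the index nearly follows the groups.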

Results

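Gene expression was measured by RNA-seq in 9 libraries of IL-4-exposed peritoneal macrophages: 3 monocyte-derived, 3 converted and 3 resident. The libraries held 15220884 to 20496258 reads in genes, with 17871 to 19922 genes read at least once. The most abundant transcript in every library was Chil3, a chitinase-like protein induced by IL-4, with 2.1% to 9.79% of reads. Mitochondrial transcripts made up 0.31% to 0.88%, with 0.31% to 0.35% in converted and 0.5% to 0.6% in resident libraries. Genes read at least once numbered 18636 to 18677 in converted and 19360 to 19922 in resident libraries. Libraries of the same group differed by more than counting noise (chi-square over degrees of freedom at least 6.03), so none was counted as a duplicate. The reporter's driver gene Cx3cr1 had 36 reads over the 9 libraries and was not tested.

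The design asks how far macrophages of recent monocyte origin take on the state of resident macrophages over time in the tissue. Converted libraries lay next to the resident ones. On a scale from 0 (monocyte-derived) to 1 (resident), held-out monocyte-derived libraries had a position of 0.043 ± 0.019, converted libraries 0.908 ± 0.024 and held-out resident libraries 0.991 ± 0.013 (SD, n = 3 each). Sex-linked transcripts also separated the monocyte-derived libraries from both other groups, so sex cannot be told apart from origin along this scale. Only the monocyte-derived group was harvested 4 days after thioglycollate, so effects of this recent irritant cannot be told apart from origin either. Gata6, the transcription factor of large peritoneal macrophages, had 1.43 ± 0.765 CPM in monocyte-derived, 160.9 ± 24.7 in converted and 160.3 ± 2.05 in resident libraries (SD, n = 3). All converted positions lay between those of the other groups, and the exact permutation test gave p = 0.1 two-sided against either group, the smallest value 3 against 3 libraries can give. Among genes higher in resident libraries the converted position was 0.813 beside 0.992 for resident libraries, and among genes higher in monocyte-derived libraries it was 1.080 beside 0.987. Transcripts of B cells moved with this gap: the B-cell list summed to 182.7 ± 76.8 CPM in converted and 1614 ± 223 in resident libraries (SD, n = 3). With the lists of other cell types left out, the converted position was 0.917, and 0.827 among genes higher in resident libraries; transcripts of other cells beyond these lists were not removed. edgeR's test over the 3 groups called 7235 of 13223 genes (54.7%).

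**Figure D1:**
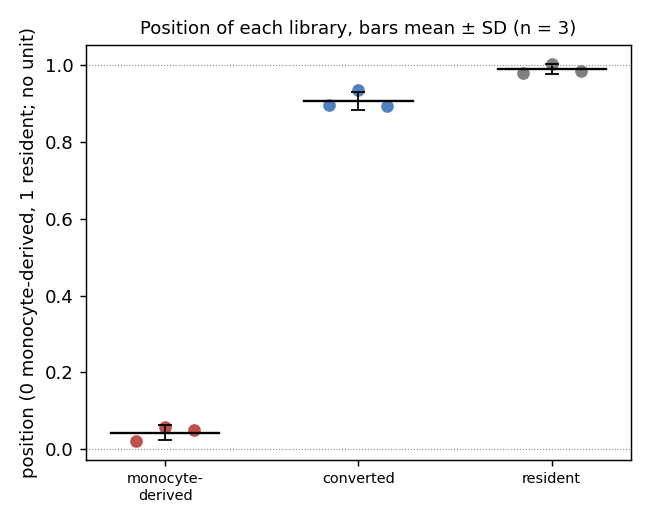
Position of each library on the axis from monocyte-derived (0) to resident (1), without unit; points are libraries, lines and bars the mean ± SD of 3. Converted libraries sit at 0.893 to 0.935, below the held-out resident libraries at 0.981 to 1.005. Sex-linked transcripts and the harvest 4 days after thioglycollate split the monocyte-derived libraries from both other groups as well.

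Converted macrophages were compared with monocyte-derived ones to ask what changed after the irritant. Per the labels only the converted group had the tamoxifen diet, so effects of the diet cannot be told apart here. Only the monocyte-derived group had the irritant 4 days before harvest, so its recent effects cannot be told apart either. Genes of resident cavity macrophages rose: 33 of 38 were higher and 1, the transcription factor Bhlhe40, was lower, at a fold of 1.24 and an adjusted p of 0.0244, which was 0.279 with the B-cell index as a covariate, 0.0867 without monocyte-derived library 3 and 0.0791 and 0.101 without converted libraries 1 and 2. Gata6 (ENSMUSG00000005836, GRCm38 chromosome 18, 11052064 to 11085635) rose 114-fold (log2 6.83 ± 0.29 SE, adjusted p = 1.59e-07). Timd4, a receptor for phosphatidylserine on dying cells (chromosome 11, 46810800 to 46844332), rose from 1.003 ± 0.595 to 105.5 ± 17.7 CPM, and Prg4, the lubricant proteoglycan, from 1.04 ± 0.114 to 1195 ± 259 CPM. Adgre1, which encodes F4/80, rose 8.96-fold. Ccr2, the chemokine receptor of recruited monocytes (chromosome 9, 124101950 to 124113557), fell from 823.3 ± 462 to 2.32 ± 0.139 CPM (adjusted p = 6.35e-07). The resident list had a camera adjusted p of 2.17e-15, and adjusted p = 0.178 with an estimated correlation; adjusted over the list alone, 33 were higher and 1 lower.

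Cell cycle genes rose as well, with 43 of 44 higher in converted libraries. Mki67, a marker of cycling cells, went from 26.9 ± 11.3 to 167.4 ± 32.2 CPM and Nusap1 from 32.6 ± 13.9 to 184.1 ± 36.6. The list had an adjusted p of 3.5e-11, and adjusted p = 0.492 with an estimated correlation. Of 33 interferon-stimulated genes 21 were higher and 1 lower, Usp18, at 1.83-fold and adjusted p = 0.0206; without monocyte-derived library 1 or converted library 1 or 3 it had 0.0631, 0.068 and 0.0754. Gbp3 rose 25.3-fold and Oas2 17.6-fold. Their list adjusted p was 2.98e-05, and adjusted p = 0.492 with an estimated correlation.

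MHC class II genes, which present antigen to T helper cells, fell: 11 of 16 were lower and 1 (the costimulator Cd80, 2.1-fold; adjusted p = 0.0669 with the B-cell index) was higher. Cd74, the invariant chain, fell from 11720 ± 1810 to 842.8 ± 115 CPM, H2-Ab1 from 4518 ± 796 to 341.2 ± 53.7 and H2-Eb1 from 1821 ± 312 to 106.2 ± 5.27 (list adjusted p = 0.000169). That was adjusted p = 0.354 with an estimated correlation. The alternative activation list moved both ways, with 22 of 35 lower and 8 higher. Pdcd1lg2, which encodes PD-L2, fell 96.6-fold, Mrc1, the mannose receptor, 22.6-fold, and the chemokine Ccl24 37.4-fold. Chil3 rose 3.11-fold and Alox15 44.7-fold. Retnla was 2.03-fold higher at an adjusted p of 0.0423, a call that ended with the B-cell index as a covariate (0.147), without monocyte-derived library 3 (0.0551), converted library 1 or 3 (0.1 and 0.108) or resident library 1, 2 or 3 (0.0592, 0.0588 and 0.0594), and with the replicate number as a block (0.0523). Arg1 had 14040 ± 1720 CPM in monocyte-derived and 13140 ± 865 in converted libraries (adjusted p = 0.528). The list's adjusted p was 0.000186, and adjusted p = 0.317 with an estimated correlation.

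Of 20 glycolysis genes 14 were lower (Pgk1 2.34-fold, Tpi1 2.45-fold, Pfkp 4.37-fold) and 3 higher (Pfkl, Pfkm, Hk1), with adjusted p = 0.000828 for the list and adjusted p = 0.317 with an estimated correlation. Complement and coagulation genes were higher for 13 of 21 and lower for 5, C4b rising 94.3-fold and F13a1 falling 108-fold (adjusted p = 0.0135). That list had an adjusted p = 0.492 with an estimated correlation, and adjusted p = 0.054 without converted library 3. Small cavity macrophage and dendritic-type genes fell for 14 of 21 and rose for 2: Ear2 fell 311-fold and Fcrls 173-fold (adjusted p = 0.000251). With an estimated correlation its adjusted p = 0.317. Among inflammatory cytokines and chemokines 14 of 28 were lower, Ccl7 by 263-fold and Ccl2 by 33.2-fold, and 9 higher (camera adjusted p = 0.175). Cxcl1 rose 153-fold, from 0, 0.46 and 0 CPM in monocyte-derived libraries 1, 2 and 3, so this fold rests on a level near none. Monocyte genes were lower for 14 of 25 and higher for 8 (adjusted p = 0.175). Matrix genes were lower for 14 of 24 and higher for 9, Ltbp1 rising 811-fold and Mmp13 falling 140-fold. Of 30 fatty acid oxidation genes 12 were higher and 5 lower; of 51 oxidative phosphorylation genes 14 were higher and 4 lower. Neither these lists nor the retinoid list (10 higher and 7 lower of 20) passed camera. The oxidative phosphorylation list had an adjusted p of 0.085, 0.0014 and 0.0292 without monocyte-derived library 2 and converted library 2, and 0.000908 with the B-cell index, with which the fatty acid oxidation list had 0.0303. By fry the cytokine, monocyte, fatty acid oxidation and retinoid lists had an adjusted p of 0.0122, 0.000513, 0.038 and 0.00327.

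Among other cell types, neutrophil genes were lower for 10 of 11 (adjusted p = 0.000342) and NK-cell genes for 10 of 10 (adjusted p = 0.000186), and B-cell genes were higher for 11 of 18 (adjusted p = 0.00131). With an estimated correlation these were adjusted p = 0.317, adjusted p = 0.492 and adjusted p = 0.492. Dendritic-cell genes were lower for 6 of 10 (adjusted p = 0.0411), T-cell genes for 4 of 16 (adjusted p = 0.0397) and ribosomal protein genes for 16 of 50 (adjusted p = 0.00164). With an estimated correlation these were adjusted p = 0.492, adjusted p = 0.666 and adjusted p = 0.689. The dendritic-cell list had 0.0591, 0.101 and 0.0522 without monocyte-derived library 1, monocyte-derived library 3 and converted library 1, and the T-cell list 0.195, 0.0745 and 0.112 without monocyte-derived library 3, converted library 1 and converted library 3. With protein-coding genes alone these lists had 0.0528 and 0.0621, and by fry the T-cell list had 0.0627. With the B-cell index the B-cell and ribosomal protein lists had 0.472 and 0.494. The first is no check, since the index is the sum of the B-cell list. Ddx3y and Eif2s3y, on chromosome Y, had no read in the monocyte-derived libraries and at least 1570-fold and 1360-fold more in the converted ones. Xist, expressed from the inactive X chromosome of females, had 64.7 ± 32 CPM in monocyte-derived, no read in converted and 2 reads in resident libraries, so the sex-linked transcripts split the libraries as this comparison does. Ctsk, a protease of osteoclasts, fell from 189 ± 158 to 0.124 ± 0.0623 CPM (adjusted p = 0.00011 by edgeR and 0.0809 by limma-voom). Adjusted over the list alone, 44 cell cycle genes were higher, 23 interferon-stimulated genes higher and 12 MHC class II genes lower. In all, 6703 genes were called, 3416 higher and 3287 lower, 3252 of them at least 2-fold (edgeR quasi-likelihood), and 3421 with the B-cell index.

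**Figure D2:**
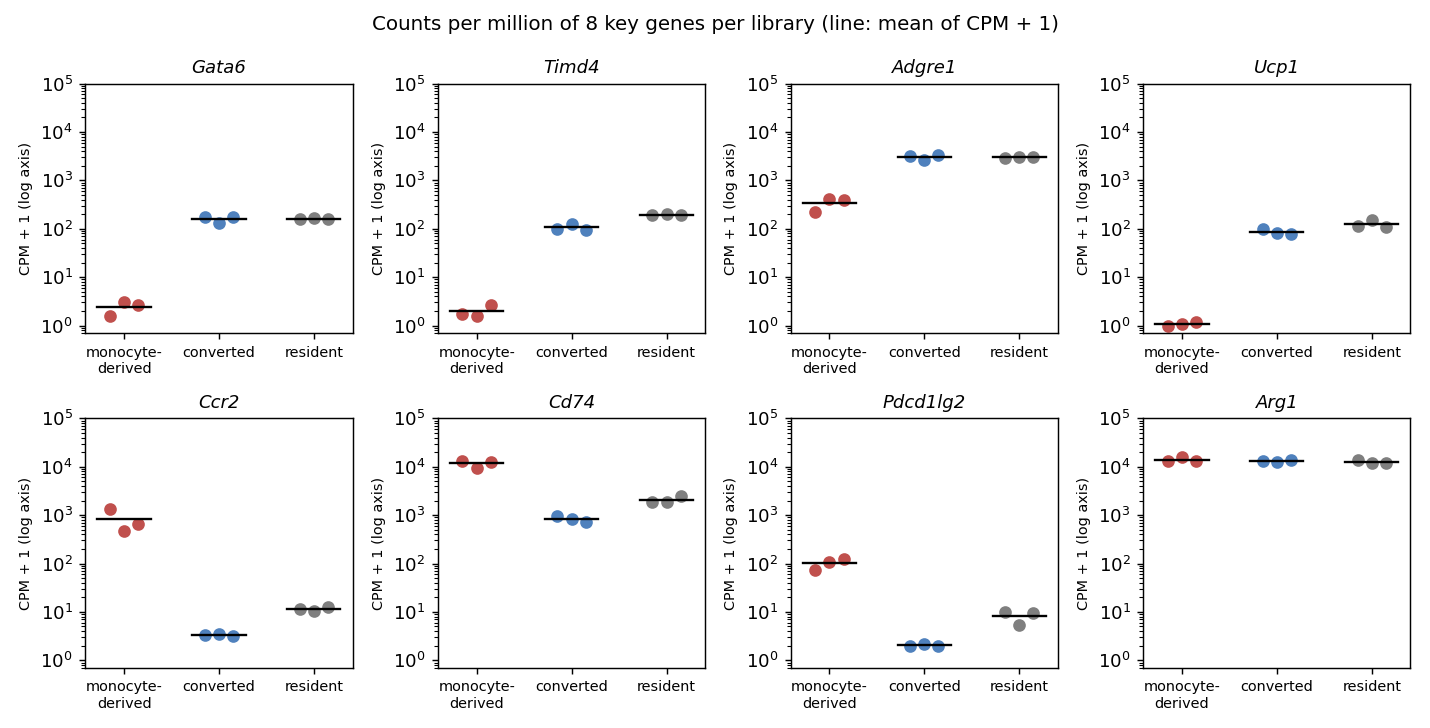
CPM + 1 (log axis) of 8 key genes in each library by group; points are libraries and lines the mean of 3. Gata6, Timd4, Adgre1 and Ucp1 are higher and Ccr2, Cd74 and Pdcd1lg2 lower in converted and resident than in monocyte-derived libraries, while Arg1 is at 11951 to 16017 CPM in all 9.

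Resident and monocyte-derived macrophages mark the ends of the scale. The labels give only the latter thioglycollate, so its effects cannot be told apart from origin here. Resident cavity genes were higher for 34 of 38 and lower for none (Timd4 195-fold, Prg4 1020-fold, Gata6 113-fold). Ucp1, the uncoupling protein of brown fat (chromosome 8, 83290352 to 83298452), rose from 0.084 ± 0.0997 to 123.9 ± 21.8 CPM. All 33 interferon-stimulated genes rose, with Oas2 42-fold and Gbp3 20.9-fold higher, and 40 of 44 cell cycle genes rose. Adjusted p was 1.64e-15, 4.78e-11 and 1.61e-07 for these lists, and adjusted p = 0.174, adjusted p = 0.334 and adjusted p = 0.679 with an estimated correlation. With the B-cell index as a covariate the cell cycle list turned direction (adjusted p = 0.0323), and the log2 changes of Mki67, Nusap1, Cenpf, Cenpe, Rrm2 and Mcm6 were -0.10, -0.15, -0.83, -0.50, -0.93 and -0.94; Oas2 and Gbp3 had an adjusted p of 0.2 and 0.0625.

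Ccr2 fell 78-fold, Mrc1 12.4-fold and Pdcd1lg2 13.4-fold in resident libraries (adjusted p = 0.177, 0.239 and 0.177 with the B-cell index). Of 16 MHC class II genes 9 were lower and 4 higher, and the list did not pass (adjusted p = 0.0505), though it did with DESeq2 size factors (0.046) and without monocyte-derived library 2 or resident library 3 (0.0382 and 0.0373), by fry (0.000319) and with the B-cell index (0.00035). Glycolysis genes were lower for 15 of 20 and higher for 3 (adjusted p = 0.00124), alternative activation genes lower for 22 of 35 and higher for 8 (adjusted p = 0.000476), and neutrophil genes lower for 10 of 11 and higher for 1 (adjusted p = 0.000173). Each had an adjusted p = 0.334 with an estimated correlation. Small cavity genes were lower for 13 of 21 and higher for 3 (adjusted p = 0.00537, and adjusted p = 0.387 with an estimated correlation). Oxidative phosphorylation genes were higher for 21 of 51 and lower for 2 (adjusted p = 0.00693, and adjusted p = 0.792 with an estimated correlation; 0.0702 without monocyte-derived library 1 and 0.054 by fry). Complement and coagulation genes were higher for 13 of 21 and lower for 6 (adjusted p = 0.0417, and adjusted p = 0.679 with an estimated correlation). That list had 0.0544 with the replicate number as a block, and did not pass without monocyte-derived library 1 or 2 (0.0863 and 0.0554), converted library 1, 2 or 3 (0.102, 0.104 and 0.104) or resident library 1, 2 or 3 (0.0886, 0.0895 and 0.0797). B-cell genes were higher for 17 of 18 (adjusted p = 4.55e-09, and adjusted p = 0.334 with an estimated correlation). Ms4a1, which encodes CD20 (ENSMUSG00000024673, chromosome 19, 11249675 to 11266241), went from 4.00 ± 1.94 to 214.1 ± 31.1 CPM. With the B-cell index the list had an adjusted p of 0.456 and Ms4a1 a log2 change of -0.15. Both follow from the index being the sum of that list. Ddx3y was at least 1550-fold higher, and the sex-linked split applies here too. The test called 6698 genes, 3400 higher and 3298 lower, with 3216 at least 2-fold; with the B-cell index it called 126 (1932 at an unadjusted p under 0.05), at a median SE of 0.807 in place of 0.168.

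Of these 6698 genes, 5449 (81.4%) were called in the same direction in converted versus monocyte-derived libraries, 20 in the opposite direction and 1229 did not pass there. Both contrasts shared 2772 higher genes against 878.3 for independent lists, and 2677 lower genes against 819.8. Fold changes of both contrasts correlated across genes at r = 0.911, against 0.512 in simulated unchanged groups that share the monocyte-derived libraries, with a covariance of 1.906 against 0.04, a difference of 1.867. With the monocyte-derived libraries split so that 1 served one contrast and 2 the other, r was 0.822 to 0.868 and the covariance 1.786 to 1.855 over the 6 ways. The simulations gave each gene the same dispersion in all groups, while the real monocyte-derived libraries spread more than the others. Sharing them may therefore raise r above the simulated 0.512. Genes are not independent replicates. Both contrasts also share the split in sex-linked transcripts and the recent irritant of the monocyte-derived group. The part of either in their agreement was not tested. The shared calls were not counted with split libraries, so part of their excess may come from sharing them.

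Converted and resident macrophages were compared to ask what still separated them. Of these groups only the converted one had the earlier thioglycollate and the tamoxifen diet. Effects of either cannot be told apart from origin here. Most markers of resident cavity macrophages did not pass: 33 of 38, with Gata6 at 160.9 and 160.3 CPM (adjusted p = 0.992) and Adgre1 at 3077 ± 377 and 2978 ± 32.7. By edgeR 5 of the 38 were called and 10 had an unadjusted p under 0.05, while DESeq2 called 5 and limma-voom 8. Over all 13223 genes 6.1% were called by edgeR. A marker that did not pass may still differ. Timd4 was lower in converted libraries, at 105.5 ± 17.7 against 192.2 ± 6.01 CPM (log2 -0.87 ± 0.18 SE, adjusted p = 0.0238), as were Wnt2 (2.28-fold) and Bhlhe41 (0.141 ± 0.198 against 2.52 ± 0.697 CPM). Itga6 and Fn1, an integrin and fibronectin, were 1.61-fold and 1.51-fold higher. By the naming rule, lipoprotein lipase, Lpl, had the largest increase, 83.6 ± 48.3 against 11 ± 3.39 CPM (adjusted p = 0.0144), with 121.8, 29.4 and 99.6 CPM in the converted libraries; it was 1478 ± 602 in monocyte-derived ones. Jam2, a junctional adhesion molecule, was 3.02-fold higher. In edgeR with the B-cell index as a covariate no gene passed in this comparison (1152 at an unadjusted p under 0.05), the median SE went from 0.165 to 0.579, and the log2 changes of Timd4 and Jam2 were 0.82 and -0.34. Leaving out 1 library, which leaves 2 in a group, ended several calls. Where it did, the log2 change was -0.88 to -0.79 for Timd4, 0.49 to 0.66 for Fn1 and 2.71 to 3.15 for Lpl. Without converted libraries 1 and 3 and resident libraries 1, 2 and 3, the adjusted p of Timd4 was 0.102, 0.0979, 0.0979, 0.0866 and 0.095, and that of Fn1 0.0991, 0.091, 0.117, 0.0628 and 0.0704. Lpl had 0.0682, 0.0598 and 0.059 without resident libraries 1, 2 and 3, and Bhlhe41 0.0569 and 0.0624 without converted library 3 and resident library 3. With the replicate number as a block Timd4 had 0.0583 and Fn1 0.0589, and by limma-voom Lpl had 0.0546.

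B-cell genes were lower in converted libraries for 16 of 18 members, and 17 adjusted over the list alone. Ms4a1 had 17.7 ± 11.3 against 214.1 ± 31.1 CPM and Ighm, the IgM heavy chain, 42.1 ± 27.4 against 545.4 ± 56.6. Summed over the list, the level was 182.7 ± 76.8 CPM in converted, 1614 ± 223 in resident and 71.1 ± 27.6 in monocyte-derived libraries. T-cell genes were lower for 9 of 16, NK-cell genes for 6 of 10 and mast-cell or basophil genes for 3 of 6, against 14, 9 and 5 adjusted over the list alone. Il5ra, on the eosinophil list, fell 8.97-fold. Camera adjusted p was 7.07e-19 for B, 8.81e-11 for T and 6.9e-09 for NK cells, and adjusted p = 0.21, adjusted p = 0.226 and adjusted p = 0.226 with an estimated correlation. Mast-cell or basophil and dendritic-cell lists (2 of 10 lower) had an adjusted p of 0.000129 and 0.000271, and adjusted p = 0.21 and adjusted p = 0.226 with an estimated correlation. With the B-cell index as a covariate the B-cell list had an adjusted p of 0.949, and the T-cell (0.0124), NK-cell (0.264), mast-cell or basophil (0.862) and dendritic-cell (0.402) lists turned direction. Ms4a1 and Ighm then had log2 changes of 0.45 and 0.22. The index is the sum of the B-cell list itself, so the values of that list and its members are no check. It also nearly follows the groups, so the turned directions of the other lists do not show which cells brought them.

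Interferon-stimulated genes fell for 14 of 33 (Usp18 3.03-fold, Stat2 2.49-fold), and MHC class II genes for 8 of 16 (H2-Eb1 2.77-fold, Cd74 2.45-fold). Immediate early and stress genes, which respond within minutes to cell handling, fell for 14 of 25; Egr1 had 11.9 ± 5.11 against 142 ± 5.33 CPM. Small cavity genes fell for 7 of 21. Ear2 was 11.1-fold lower (2.48 against 27.5 CPM) and Itgax 7.96-fold, at low levels in both groups (0.237 against 1.87 CPM). Adjusted p was 7.05e-12, 3.65e-08, 9.44e-09 and 1.51e-05 for these lists, and adjusted p = 0.226, adjusted p = 0.21, adjusted p = 0.226 and adjusted p = 0.21 with an estimated correlation. Adjusted over the list alone, 27 interferon-stimulated genes were lower and 1 higher, and 10 MHC class II, 14 immediate early and 8 small cavity genes were lower. These are the libraries in which B-cell transcripts also stood lower. The B-cell index nearly follows the groups and raised edgeR's median SE from 0.165 to 0.579 here. A list that no longer passes with it therefore does not show that B cells account for that list. With the B-cell index as a covariate the interferon, MHC class II and small cavity lists had an adjusted p of 0.596, 0.402 and 0.897, the alternative activation and cholesterol synthesis lists 0.203 and 0.696, while the immediate early list passed. Within alternative activation 4 of 35 members fell, among them Pdcd1lg2 (7.2-fold) and Il4ra (2.01-fold), while Arg1, Chil3 and Retnla did not pass (list adjusted p = 0.00611, and adjusted p = 0.226 with an estimated correlation). Inflammatory cytokine and chemokine genes were lower for 4 of 28 (Ccl2 3.22-fold) and ribosomal protein genes for 4 of 50, against 10 and 23 adjusted over the list alone. Their adjusted p was 0.000117 and 7.13e-10, and adjusted p = 0.314 and adjusted p = 0.475 with an estimated correlation (0.0952 and 0.0518 by fry). Ucp1 was at 84.6 ± 11.4 and 123.9 ± 21.8 CPM (adjusted p = 0.0969 by edgeR, 0.0312 without monocyte-derived library 1 and 0.0277 by DESeq2). Aldh1a2, which makes retinoic acid, was 3.84-fold lower and Cyp26b1, which degrades it, 2.62-fold higher, at adjusted p of 0.036 and 0.0386. Aldh1a2 did not pass without monocyte-derived library 1 or 2 (0.0538 and 0.055), converted library 1 or 3 (0.0724 and 0.121) or resident library 1, 2 or 3 (0.126, 0.0752 and 0.121). Cyp26b1 did not pass without converted library 1, 2 or 3 (0.136, 0.0751 and 0.12) or resident library 1, 2 or 3 (0.0728, 0.146 and 0.185). With the replicate number as a block they had 0.0502 and 0.0548, and with the B-cell index log2 changes of 1.31 and -0.31. No cell cycle gene of 44 was called by edgeR; 15 had an unadjusted p under 0.05, and DESeq2 called 3 and limma-voom 2. Camera ranked that list up (adjusted p = 1.23e-07, and adjusted p = 0.681 with an estimated correlation; 0.359 by fry). Of 24 cholesterol synthesis and 51 oxidative phosphorylation genes edgeR, DESeq2 and limma-voom called 0, with 7 and 10 at an unadjusted p under 0.05. Camera placed both lists down (adjusted p = 0.00104 and 0.0317, and adjusted p = 0.71 and adjusted p = 0.906 with an estimated correlation). The cholesterol list had 0.0986 without converted library 3 and 0.359 by fry. The oxidative phosphorylation list had 0.536 by fry, 0.059 with the replicate number as a block, and 0.0567, 0.323, 0.117, 0.113 and 0.0675 without monocyte-derived library 3, converted libraries 2 and 3 and resident libraries 1 and 2.

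edgeR called 803 genes, 240 higher and 563 lower, 18 and 435 of them at least 2-fold. Of these, 450 placed the converted libraries on the monocyte-derived side of the resident ones and 171 beyond them, among genes that also passed in resident versus monocyte-derived. On the monocyte-derived side 343 were lower and 107 higher, against 144.8 and 59.9 for independent lists. Beyond the resident libraries 116 were lower and 55 higher, against 140.4 and 61.7. Both comparisons use the resident libraries, so part of the excess may come from sharing them. With 1 library left out the count was 1628 (751 higher, 46.1%) without monocyte-derived library 1, 361, 535 (88 higher, 16.4%) and 354 without converted libraries 1, 2 and 3, and 295 (24 higher, 8.1%), 400 (79 higher, 19.8%) and 245 (24 higher, 9.8%) without resident libraries 1, 2 and 3. A strict filter called 406, the replicate block 530, DESeq2 1314, a fit of these 6 libraries alone 2067 (900 higher, 43.5%) and the fit with the B-cell index 0. Upper quartile scaling called 739, with 18% higher in place of 29.9%.

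**Figure D3:**
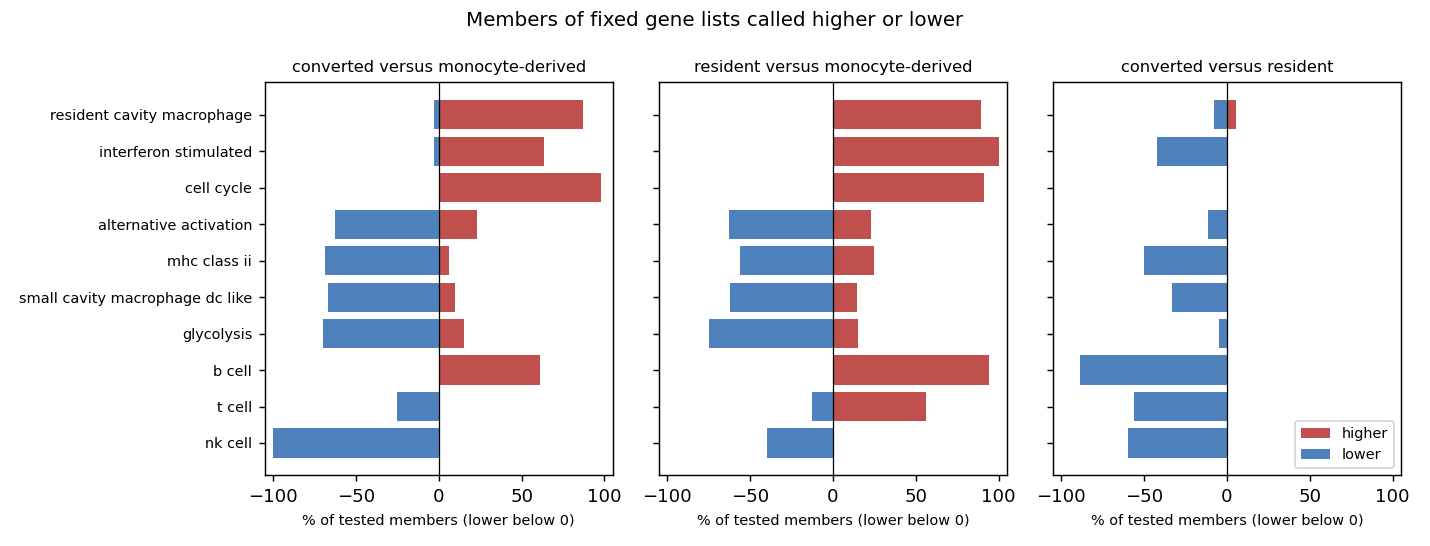
Share of tested members (%) called higher (red) or lower (blue, drawn below 0) for 10 fixed lists in the 3 comparisons. Resident cavity genes are higher for 33 and 34 of 38 against monocyte-derived libraries, and B-cell genes lower for 16 of 18 in converted versus resident.

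**Figure D4:**
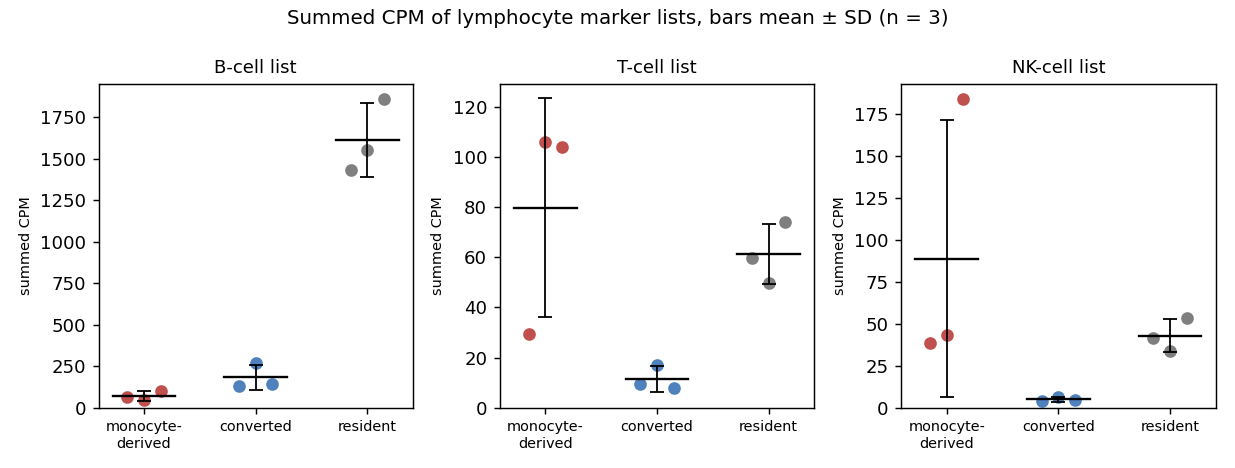
Summed CPM of the B-cell, T-cell and NK-cell lists in each library; points are libraries, lines and bars the mean ± SD of 3, axes start at 0. The B-cell sum is 1429 to 1861 CPM in resident and 132.1 to 271.1 in converted libraries.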

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

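Chosen after seeing the data were the fit without genes on chromosomes X and Y, the fit with a B-cell index, positions without the lists of other cell types and the split of monocyte-derived libraries between contrasts. Each count of the comparisons against monocyte-derived libraries stayed within 1.5 times under every other scaling, filter, tool and left-out library run, and no gene called in any of the 3 comparisons turned its sign under them. Requiring a 2-fold change left 3252, 3216 and 453 genes in converted versus monocyte-derived, resident versus monocyte-derived and converted versus resident. The last comparison moved most: 406 genes with a strict filter, 1314 with DESeq2, 2067 in a fit of its 6 libraries alone, and 245 to 1628 with 1 library left out. With the strict filter 265 of the 803 calls were not tested and 135 were tested but did not pass. Fits of 6 libraries alone lowered the other counts, to 5496 and 6109. The 2067 came without the monocyte-derived libraries, and the 1628 without library 1 of that group. Pairs within that group had a chi-square over degrees of freedom of 35.51 to 104.64, against 6.03 to 24.24 within the others. The fits with 2067 and 1628 calls kept 785 and 802 of the 803. Without monocyte-derived library 2 or 3 the count rose as well, to 918 and 983. The count of 803 thus depends on the monocyte-derived libraries in the fit, and rose whenever any of them was left out. Their spread was not varied apart from this. For converted versus resident the replicate block gave 530. Between libraries of different groups, deviations from the group mean correlated at -0.094 to 0.065 with the same number. With different numbers they correlated at -0.089 to 0.106. The numbers are therefore not treated as pairs, and the cause of the lower count was not tested. With an estimated correlation 0, 0 and 0 gene lists passed in place of 14, 10 and 15, and with fry 19, 14 and 10. The converted position was 0.963 as a median over genes, 0.813 on genes higher in resident (0.827 without the lists of other cell types) and 1.080 on genes higher in monocyte-derived libraries, and 0.892 to 0.921 with 1 library left out. The agreement of contrasts was 0.947 at a mean of at least 5 CPM, 0.895 to 0.913 with 1 library left out, and on average 0.838 with the monocyte-derived libraries split between the contrasts (fewer libraries set each mean and none is shared; the cause was not tested apart). Of 10072 values of named genes under alternatives, 9520 kept their direction and side of the threshold, 419 no longer passed and 85 passed in addition. Depth was not varied; 1.5-fold changes were mostly missed on simulated counts.

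The index is the log2 summed CPM of the B-cell list, and it nearly follows the groups: the median standard error rose from 0.168 to 0.284, from 0.168 to 0.807 and from 0.165 to 0.579 in the 3 comparisons. edgeR then called 3421, 126 and 0 genes (5138, 1932 and 1152 at an unadjusted p under 0.05), and 16 lists in resident versus monocyte-derived and 9 in converted versus resident. Of the calls without it, 39, 1365 and 199 had the opposite sign, none past the threshold; DESeq2 and limma-voom were not run with it. The log2 changes of named genes that turned sign were, in converted versus monocyte-derived, Mzb1 -0.51, Cd79b -0.44; in resident versus monocyte-derived, Mki67 -0.10, Nusap1 -0.15, Cenpf -0.83, Cd36 0.12, Usp18 -1.30, Ndufa4 0.51, Cenpe -0.50, Cebpa 0.17, H2-Ob -1.42, H2-Oa -1.40, H2-Eb2 -2.36, Cd209a -1.79, Slc43a3 -0.081, Ikzf3 -1.84, Mzb1 -1.31, Cd209b -2.09, Ms4a1 -0.15, Cd79b -0.46, Rrm2 -0.93, Mcm6 -0.94, Cd55 -0.40, Stat2 -0.40, Plac8 -1.77, Bhlhe41 -1.16, Lyz2 0.68, Ighm -1.73, Hdc -0.08, Krt18 -2.53; and in converted versus resident, Timd2 0.24, Cyp26b1 -0.31, Aldh1a2 1.31, Timd4 0.82, Msr1 -0.38, Ddx58 0.24, Jam2 -0.34, Vill -1.35, Ikzf3 0.45, Mzb1 0.80, Cd209b 3.87, Ms4a1 0.45, Cd79b 0.018, Cd55 1.61, Pfkfb3 0.26, Plac8 0.34, Ighm 0.22, Gzma 1.16. Lists that turned direction were cell cycle in resident versus monocyte-derived (adjusted p = 0.0323), and in converted versus resident the dendritic-cell (0.402), mast-cell or basophil (0.862), NK-cell (0.264) and T-cell lists (adjusted p = 0.0124).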

Other observations

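Chosen after the results were seen were the test of a mixture with monocyte-derived-type cells and both tests on sex-linked transcripts. The 13 osteoclast genes were listed after Ctsk and Dcstamp had been seen, and before their own values were.

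Monocyte-derived libraries held transcripts of cell fusion and of osteoclasts, the bone-resorbing relatives of macrophages: Dcstamp, needed for fusion, had 39.9 ± 23.8 CPM there and 0.0341 ± 0.0296 in converted libraries. The hypothesis that a wider osteoclast programme is higher there was tested on 13 further osteoclast genes, of which 10 were tested. In resident versus monocyte-derived libraries 6 were lower, among them Acp5 (220.7 against 22.7 CPM) and Itgb3 (118.7 against 25.6), and 1, Nfatc1, was higher. As a list they missed the threshold set for them (camera p = 0.0634, and p = 0.319 with an estimated correlation), while in converted versus monocyte-derived libraries, for which no threshold had been set, p was 0.0373 (p = 0.269 with an estimated correlation). A wider programme is thus not shown, and not ruled out for the 6 lower genes. Within the monocyte-derived group library 1 stood apart: Gpnmb had 122.7, 2067 and 981.8 CPM and Retnla 8186, 27387 and 23540 in libraries 1, 2 and 3.

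The 563 genes lower in converted than in resident libraries came with lower B-cell transcripts (Ighm 42.1 against 545.4, Ms4a1 17.7 against 214.1 and Cd79a 16.6 against 176.3 CPM), although the macrophages had been sorted, which should remove most B cells. If B cells in the resident libraries may account for them, each gene should follow the B-cell sum within groups: predicted over observed differences had a median of 0.693 over the 547 genes off the B-cell list (quartiles -0.109 and 1.354; 0.619 to 1.115 with 1 library left out), and 1.159 over the 16 on it. B-cell RNA thus stays a candidate for part of these genes. A lower quartile of -0.109 shows that many did not follow the B-cell sum, and single genes stay open. The slopes rest mostly on the resident libraries, where that sum varied most (SD 223 CPM, against 76.8 in converted libraries). Within that group the T-cell and NK-cell sums were also highest in library 3, so the slopes cannot tell B cells from other lymphocytes. T-cell and NK-cell list members were lower too (15 of 26), and whether B cells or other lymphocytes brought them was not tested. Both lists turned direction with the B-cell index as a covariate (camera adjusted p = 0.0124 and 0.264). The index nearly follows the groups, so this turn does not decide which cells brought them. A further test took the 116 of these genes that were also lower in resident than in monocyte-derived libraries. A single share of monocyte-derived-type cells, as their only source, is argued against. The share needed differed at least 17.3-fold between the 90th and 10th percentile of genes. The test allowed for no other cells, so such a share together with lymphocyte RNA stays open. A difference between converted and resident macrophages themselves, or one from the treatments of the converted group, stays open too. So does a difference in handling. Immediate early and stress genes were lower for 14 of 25. Mitochondrial transcripts made up 0.31% to 0.35% in converted and 0.5% to 0.6% in resident libraries. None of these was tested apart from the other cells.

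Sex-linked transcripts separated the monocyte-derived group from both others, and 0 of 9 libraries departed from the pattern of their group. The pattern had been seen before, so this count restates it and is no separate test. It shows no sign of single libraries exchanged between monocyte-derived and other groups. Exchanges between converted and resident libraries could not show in it. The labels give no sex. Sex of the mice cannot be told apart from origin in both comparisons against monocyte-derived libraries, since the groups and the sex-linked pattern are the same split; 3.1% of the genes called in converted versus monocyte-derived lay on chromosomes X and Y, against 3.2% of those tested. Converted and resident libraries did not differ in this pattern.

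Other splits of the libraries were counted. Of 100 splits of the 9 libraries into 3 groups of 3, drawn from 280, 1 (the real split) gave as many genes as the 7235 called, and the highest other gave 5376. A random split of these libraries thus rarely gives as many calls over the 3 groups. Libraries of a group may come from the same mouse, so this does not address chance between mice. For each pair of groups 10 splits exist, too few for a share under 0.05: the real split, 1 of 10, called 6703 genes in converted versus monocyte-derived, 6698 in resident versus monocyte-derived and 803 in converted versus resident, and the highest other split called 0 in each.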
